A study of Mus musculus with 9 samples.

How the data were processed

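Lungs of 9 mice were profiled as poly(A)-selected, stranded RNA libraries on a NovaSeq X Plus, per the labels' protocols, with 3 mice in each of 3 groups (control, CuO and CuO_TTM). Groups and replicate numbers were taken from the labels. The authors deposited a single table of TPM values, a measure of transcript abundance, for 57010 Ensembl gene identifiers and 9 libraries, printed to 2 decimals. Per the submitters' processing notes, the tools named are fastp, HISAT2, RSEM and DESeq2 and the genome build is GRCm39, without versions, and how they were combined is not given in the sources used here. The TPM of every library sum to the same total, so the table keeps no depth, and no interval for counting error was computed. TPM divide by transcript length and by the sum over all genes, so that a gene holding a large share, such as Scgb1a1, lowers the values of all others in its library.

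Before the data were examined, a count test was planned for a table of counts and limma for a table of TPM. Since the table holds TPM, limma was used, and no count model was fitted. The reference annotation at hand is of the build GRCm38, not that of the table, so no coordinates are given. It served only for gene symbols, which matched 52029 of the 57010 identifiers, and for transcript length and GC content, available for 98.3% of the tested genes.

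All computations were made in R 4.3.3 with limma 3.58.1. TPM were transformed to log2(TPM + 1) with a pseudocount of 1, and genes with at least 1 TPM in at least 3 libraries were kept, which left 15487. A linear model with a mean per group was fitted to all 9 libraries, with empirical Bayes moderation and a trend on abundance, and p-values were adjusted by Benjamini and Hochberg within each comparison at 0.05 with no minimum fold change. The comparisons were CuO against control, CuO_TTM against CuO, CuO_TTM against control, and an F test of any difference. limma p-values set a group difference against the spread between mice, which is pooled over the 3 groups and moderated across genes. The same procedure was tested on simulated data, 5 draws with 200 changed genes each among 15487, in the comparison of CuO with control. It called 81.6% of genes changed by 3 and 86.4% of those changed by 4 on the log2 scale, and 35 of 76435 unchanged genes. Negative simulated values were raised to the floor of the scale. Falls of genes of low abundance could thus be smaller than the size they were counted under. Noise in these draws was independent between genes, so they do not show what variation shared by many genes of a library does to the calls. In 5 separate draws, the same few lists were each shifted by 1 on the log2 scale, again with noise independent between genes. Of these 20 shifts 19 were called, and 1 unshifted list was called as well.

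Before the data were examined, 28 lists of pathway genes and 30 lists of cell type markers were fixed, of which 52 had at least 5 tested genes. Each list was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists within a comparison. A camera p-value compares the genes of a list with all other genes. A fry p-value sets them against no change. It was computed only on TPM without further scaling, so a shift of all genes enters it. Beside the count of genes past the threshold over all genes, the count adjusted over the list alone is given. To show what chance gives for genes, for lists and for comparisons that share libraries, 100 sets of libraries without a group effect were simulated from the residuals. These sets keep the correlation between genes. The residuals of all libraries were mixed at random, so the deviation of CuO replicate 1 enters every simulated library. No simulation was run without it.

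Genes were named by a rule fixed in advance. For each comparison it takes up to 10 higher and 10 lower genes with the largest fold changes among those past the threshold whose groups do not overlap and whose mean is at least 1 TPM, leaving out predicted genes and antibody and T cell receptor segments. It adds the 3 genes of smallest p in each list described, and a fixed set of copper, stress, matrix, epithelial and cytokine genes. Genes with near-identical copies, such as the globin genes, Hspa1a and Hspa1b, Ear1 and its family members, and antibody and receptor segments, are uncertain, since reads can be shared between copies.

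The alternatives planned before the data were examined were quantile normalization, a pseudocount of 0.1, no filter, a mean of at least 5 TPM, no trend, robust moderation, a minimum log2 fold change of 1, a fit of the 2 groups compared alone, the replicate number as a block, leaving out each library in turn, and the other list tests. Those added after seeing the data were median-ratio scaling, leaving out Scgb1a1, removing each library's trend with transcript length and GC content, library weights, leaving out CuO_TTM replicates 2 and 3 together, and an estimated correlation with these or CuO replicate 1 left out. No pair of libraries held identical values.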

Results

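RNA was measured in the lungs of 9 C57BL/6J mice, an inbred laboratory strain, in 3 groups of 3. The CuO group received a single instillation of copper oxide nanoparticles into the trachea, 100 µl at 2 mg/mL, and the control group received 100 µl of saline. The CuO_TTM group received the same particles and TTM at 0.02 mg/mL in the drinking water. TTM is not spelled out in the labels. Lungs were taken on day 7, and each library comes from a different mouse. Values were TPM, a unit of transcript abundance that fixes every library at the same total, so the sequencing depth behind each value is unknown. Fold changes are differences of log2(TPM + 1) and understate the change of genes of low abundance. The abundance filter left 15487 genes, which were tested.

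The libraries differed in composition. Scgb1a1 (ENSMUSG00000024653), the main secretory protein of club cells in the airways, made up 17.3% to 22.5% of the TPM in the control libraries and 6.90% to 12.3% in the CuO libraries. In CuO_TTM it made up 8.17%, 0.180% and 0.353% in replicates 1, 2 and 3. Ciliated cell and club cell lists were both low in CuO_TTM replicates 2 and 3, with means of -2.32 and -2.27 (ciliated) and -3.72 and -3.32 (club) on the log2 scale relative to the control mean. CuO replicate 1 correlated with the other libraries at 0.864 to 0.901 across genes, and its median gene lay at -0.53 relative to the mean of all libraries, against -0.16 to 0.26 for the other libraries. Genes are not independent replicates, and these correlations only describe the libraries.

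The comparison of CuO with control asks what the particles changed in the lung. The lists of proliferation, extracellular matrix and lipid-laden macrophage genes had median log2 differences of 1.07, 0.97 and 1.24, with 30 of 30, 28 of 31 and 16 of 19 genes above 0, but no single gene passed the test across all genes. The list calls were lost when the correlation was estimated (adjusted p = 0.445 each with an estimated correlation). Col1a1 (ENSMUSG00000001506), a chain of type I collagen, measured 282 ± 58.3 TPM in CuO and 58.6 ± 5.50 TPM in control (mean ± SD, n = 3 each), a log2 difference of 2.23 (SE 0.27, limma adjusted p = 0.124). Cdk1 (ENSMUSG00000019942), the kinase that drives entry into mitosis, measured 67.3 ± 6.74 and 18.4 ± 1.01 TPM (log2 difference 1.81, adjusted p = 0.124). For both genes all 3 CuO libraries lay above all 3 control libraries. Trem2, a lipid receptor of macrophages, measured 84.3 ± 32.8 against 6.55 ± 3.20 TPM (log2 difference 3.54, adjusted p = 0.133), and the macrophage glycoprotein gene Gpnmb (ENSMUSG00000029816) 156 ± 103 against 10.1 ± 5.79 TPM (log2 difference 3.63, adjusted p = 0.184).

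limma called 0 of 15487 genes in this comparison, with or without the trend on abundance, where 1231 genes had an unadjusted p under 0.05 and 12.9% of genes had groups that did not overlap, against 10% by chance. In simulated data, the same test called 59.6% of genes changed by 2 on the log2 scale and 11.6% of those changed by 1. The sample size was the same there, noise was independent between genes, and values under 0 were set to 0. Libraries simulated from the residuals without any effect gave a median of 0 called genes, but up to 8401 in a single draw. Without CuO replicate 1 it called 35 genes, all higher in CuO, among them Col1a1, Col1a2, Col3a1, Gpnmb, Cdk1, Plk1, Top2a and Mmp14, a membrane-bound matrix protease. CuO replicate 1 itself lay above all 3 controls for 29 of these 35 genes. These 35 genes were listed after their values were seen.

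Of the 52 gene lists tested, 26 were called in CuO against control by camera with a preset correlation, 10 higher and 16 lower. The proliferation list had a median log2 difference of 1.07, and 18 of its 30 genes passed when adjusted over the list alone, against 0 over all genes (camera adjusted p = 3.4e-26, but adjusted p = 0.445 with an estimated correlation). The list of extracellular matrix and fibrosis genes had a median of 0.97, and 11 of 31 passed when adjusted over the list alone, led by Col1a1, the elastic fibre gene Eln (2.57) and Col1a2 (1.71), against 0 over all genes (adjusted p = 0.445 with an estimated correlation). The list of alternatively activated and lipid-laden macrophage genes had a median of 1.24, with 9 of 19 higher when adjusted over the list alone and 0 over all genes, led by Trem2, Gpnmb and the fatty acid binding protein Fabp5 (1.47). Its adjusted p was 0.445 with an estimated correlation. Monocyte and interstitial macrophage genes (median 0.68) included the complement genes C1qa (1.84) and C1qb (1.89), and 4 of 16 were higher when adjusted over the list alone, 0 over all genes (adjusted p = 0.512 with an estimated correlation). Lysosome genes (median 0.46) were led by the proteases Ctsz (1.41) and Ctsd (2.03), with 6 of 20 higher over the list alone and 0 over all genes (adjusted p = 0.516 with an estimated correlation). Lists of transitional epithelium, matrix proteases, complement, oxidative phosphorylation and ferroptosis genes were also called higher, with adjusted p from 0.445 to 0.569 with an estimated correlation. The calls of oxidative phosphorylation and ferroptosis were lost with quantile normalization (adjusted p = 0.0995 and 0.0674). Without CuO replicate 1, the genes higher over the list alone were 30 of 30 (proliferation), 17 of 31 (matrix), 11 of 15 (matrix proteases, in place of 2), 8 of 16 (monocytes) and 14 of 20 (lysosome), with 6, 3, 2, 1 and 1 over all genes. The medians of these lists without it were 1.37, 1.46, 1.61, 1.30 and 0.92, and those of complement and ferroptosis genes 1.02 and 0.70 in place of 0.41 and 0.37. Interferon-stimulated, glycolysis and TCA cycle lists, uncalled with all libraries, were called higher without it (medians 1.64, 0.78 and 0.36, camera adjusted p = 0.0465, 0.00326 and 0.0209). In that fit these calls too were lost with an estimated correlation (adjusted p = 0.776, 0.66 and 0.515 with an estimated correlation).

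Among the lists called lower, the alveolar macrophage list had a median of -1.02, with Ear1 at -4.42, a ribonuclease gene with a near-identical family member, and Fabp1 at -3.23. When adjusted over the list alone, 2 of its 14 genes were lower, against 0 over all genes (adjusted p = 0.458 with an estimated correlation). Xenobiotic metabolism genes had a median of -1.20, with the monooxygenase genes Cyp4b1 (-2.04) and Fmo1 (-1.25) the 2 of 18 lower when adjusted over the list alone and 0 over all genes (adjusted p = 0.445 with an estimated correlation). Capillary genes (median -0.83), with the endothelin receptor Ednrb at -1.81, and natural killer cell genes (median -1.27), with 2 of 12 and 4 of 11 genes lower over the list alone and 0 over all genes, each had an adjusted p of 0.445 with an estimated correlation. Without CuO replicate 1, 0 of 11 natural killer cell genes were lower over the list alone (median -0.87), and 5 of 18 xenobiotic genes were (median -0.76). The medians of heat shock, mesothelial, club and neutrophil lists were -0.02, -0.42, -0.46 and -0.47 without it, in place of -0.37, -0.89, -0.82 and -0.74. Lists of endothelial, B, T, erythroid, platelet, neutrophil, eosinophil and mast, club, mesothelial and cardiac cells, of heat shock genes and of immediate early genes were also called lower, with adjusted p from 0.445 to 0.797 with an estimated correlation. Of these, the calls of T, club and cardiac cells were lost with quantile normalization (adjusted p = 0.116, 0.14 and 0.0674), and that of T cells also without CuO_TTM replicates 2 and 3 (adjusted p = 0.0606). No list was called with an estimated correlation or by fry, where the smallest adjusted p was 0.0622. In libraries simulated without any group effect, camera called a median of 19 lists and as many as 26 in 18 of 100 draws.

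With all 9 libraries, no gene of the copper handling list was called in any of the 3 comparisons (limma; 0 also when adjusted over the list alone). Without CuO replicate 1, 3 of its genes were called higher and 1 lower in CuO_TTM against control (4 and 1 adjusted over the list alone), among them Loxl2 (1.31), a lysyl oxidase homologue, and Atp7b (-1.13). This comparison contains no CuO library, so its fold changes are the same with all 9 libraries, and only the pooled spread and the libraries behind it changed. The metallothionein gene Mt1, whose protein binds copper and zinc, measured 228 ± 74.9 TPM in CuO, 137 ± 103 TPM in control and 202 ± 68.9 TPM in CuO_TTM (n = 3 each), with a log2 difference of 0.91 for CuO against control and -0.18 for CuO_TTM against CuO (limma adjusted p = 0.728 and 0.952). With single libraries left out, the first difference was 0.60 without control replicate 1 and 1.48 without control replicate 3, and the second -0.49 without CuO replicate 3 and 0.14 without CuO_TTM replicate 2, all uncalled. The copper importer gene Slc31a1 differed by -0.25 in CuO against control (95% interval -1.17 to 0.66) and by 0.19 in CuO_TTM against CuO (-0.72 to 1.10), and both differences changed sign without CuO replicate 1 and stayed uncalled. The exporter gene Atp7b differed by -0.90 and -0.23 in the same comparisons (adjusted p = 0.605 and 0.911). These were -0.56 and -0.58 without CuO replicate 1, and the second was 0.15 without CuO replicate 3, all uncalled. The lists of copper handling genes and of cuproptosis and lipoylation genes had medians of 0.29 and 0.00 in CuO against control (camera adjusted p = 0.149 and 0.996). In CuO_TTM against CuO the medians were 0.18 and 0.23 (adjusted p = 0.539 and 0.743), and in CuO_TTM against control 0.40 and 0.34 (adjusted p = 0.482 and 0.789). The medians without CuO replicate 1 were 0.41 and 0.29 in CuO against control and turned to -0.07 and -0.13 in CuO_TTM against CuO, all uncalled.

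**Figure D1:**
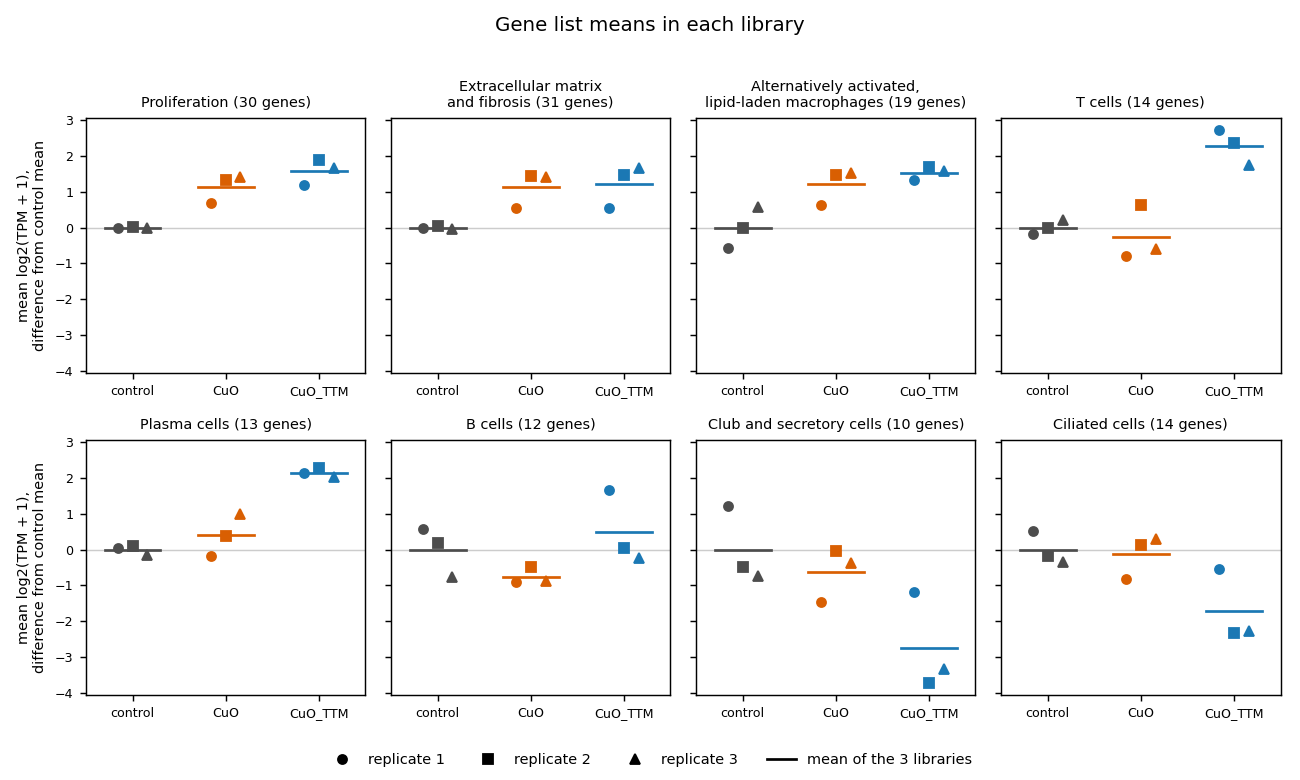
Mean log2(TPM + 1) of the tested genes of 8 lists in each library, as the difference from the mean of the 3 control libraries, with 1 point per library and a bar at the mean of each group. T cell list means were 1.74 to 2.72 in CuO_TTM and -0.79 to 0.63 in CuO, and ciliated and club cell means were lowest in CuO_TTM replicates 2 and 3.

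The comparison of CuO_TTM with CuO asks what TTM in the water changed in lungs that had received the particles. The T cell and plasma cell lists had higher means in each of the 3 CuO_TTM libraries than in any CuO library (adjusted p = 0.259 each with an estimated correlation). The genes of both chains of the CD8 co-receptor, Cd8b1 and Cd8a, measured 109.9 ± 30.2 and 82.0 ± 20.3 TPM in CuO_TTM and 7.35 ± 5.98 and 6.45 ± 5.07 TPM in CuO (n = 3 each), log2 differences of 3.92 (SE 0.43) and 3.65 (SE 0.42), each with a limma adjusted p of 0.0156. The T cell receptor complex gene Cd3g was higher by 3.03, the chemokine receptor gene Cxcr6 by 3.55, the inhibitory receptor gene Pdcd1 by 3.29 and the granule genes Nkg7, Gzmk and Ctsw by 3.22, 3.14 and 3.12. Marco, a scavenger receptor of macrophages, measured 35.5 ± 22.8 TPM in CuO_TTM and 1.91 ± 2.13 TPM in CuO (log2 difference 3.63, adjusted p = 0.0425). The CuO libraries held 0.68, 0.67 and 4.37 TPM of Marco. In control it measured 6.97 ± 3.87 TPM, and CuO_TTM against control was not called (limma adjusted p = 0.143). The antibody light chain gene Igkc (ENSMUSG00000076609) was higher by 2.55 and Mzb1, a gene of antibody-secreting cells, by 2.58.

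Of 15487 genes, limma called 107 higher and 3 lower, and 1200 had an unadjusted p under 0.05. In libraries simulated from the residuals without any effect, the median count was 0, but 4 of 100 draws gave at least 110 calls and the largest gave 7291. The groups did not overlap in 11.8% of genes, against 10% by chance. Antibody and T cell receptor segments made up 47 of the 110, and reads of these similar segments can be shared among them. The genes that fell were Meig1, by -3.54 on the log2 scale (adjusted p = 0.0439), Morn5 (-2.09) and Nnat (-1.93, adjusted p = 0.0429). In CuO_TTM replicates 1, 2 and 3, Meig1 measured 5.89, 0.55 and 0 TPM, and Morn5 1.5, 0.41 and 0.17 TPM. Both genes were lowest in replicates 2 and 3, like the ciliated and club cell lists, and Nnat was not. For Meig1 and Morn5, replicate 1 also lay below every CuO library. Nnat measured 70.9 ± 26.1 TPM in CuO, 11.1 ± 2.49 TPM in control and 17.5 ± 4.91 TPM in CuO_TTM. The T cell list had a median log2 difference of 2.70, with 13 of 14 genes higher when adjusted over the list alone and 9 over all genes, and the plasma cell list a median of 2.13, with 9 of 13 higher over the list alone and 6 over all genes. Both lists were called by fry (adjusted p = 0.0231 each), and both had an adjusted p of 0.259 with an estimated correlation. Genes of MHC class II presentation (median 1.01) were led by H2-Ab1 (1.26) and H2-Aa (1.17), and 9 of 11 were higher over the list alone, 0 over all genes (adjusted p = 0.353 with an estimated correlation). Natural killer, B and dendritic cell lists had medians of 1.06, 1.35 and 0.61, and 5, 0 and 1 of their genes were higher over the list alone, 1, 0 and 0 over all genes (adjusted p = 0.732, 0.732 and 0.373 with an estimated correlation). When CuO replicate 1 was left out, 4 T cell and 4 plasma cell genes were called over all genes, in place of 9 and 6, and 2 natural killer cell genes passed over the list alone, in place of 5. The B cell list stood at 1.65 in CuO_TTM replicate 1 and at 0.05 and -0.24 in replicates 2 and 3, relative to the control mean, against -0.91 to -0.50 in the CuO libraries. Replicate 1 also had the lowest means of the 9 libraries for alveolar type 1 (-0.95), alveolar type 2 (-0.86) and surfactant genes (-0.67).

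Airway lists were lower in CuO_TTM than in CuO. The ciliated cell list had a median of -1.77, with 8 of 14 genes lower over the list alone and 0 over all genes, and the club cell list a median of -1.72, with 4 of 10 lower over the list alone and 0 over all genes (adjusted p = 0.259 each with an estimated correlation). Both were low in CuO_TTM replicates 2 and 3, while replicate 1 stood at -0.54 (ciliated) and -1.18 (club). These values lay within the range of the CuO libraries only through CuO replicate 1 (-0.82 and -1.47). CuO replicates 2 and 3 stood at 0.14 and 0.29 (ciliated) and at -0.03 and -0.37 (club). The lowest controls stood at -0.36 and -0.73. With CuO_TTM replicates 2 and 3 left out together, the medians were -0.46 (ciliated) and -0.19 (club), and those of T cells and plasma cells 3.01 and 1.97. In that fit 9 of 11 natural killer and 8 of 12 B cell genes were higher over the list alone, and 1 of 11 MHC class II genes. Camera called 18 lists in all, 9 higher and 9 lower, and the split moved to 10 and 5 with quantile normalization. The others were proliferation, glycolysis and mesothelium, higher, and goblet cell, neutrophil, erythroid, interferon-stimulated, xenobiotic, junction and NRF2 lists, lower (adjusted p from 0.259 to 0.952 with an estimated correlation). The erythroid, xenobiotic, junction and NRF2 calls were lost with quantile normalization (adjusted p from 0.0975 to 0.191). With CuO_TTM replicates 2 and 3 left out, the interferon-stimulated list turned from a median of -0.55 to 1.45 and was called higher (camera adjusted p = 0.0021, but adjusted p = 0.87 with an estimated correlation), and proliferation stood at -0.01 in place of 0.44 (adjusted p = 0.89). Alveolar type 1, alveolar type 2, surfactant and fibroblast lists, uncalled with all libraries at medians of 0.01, 0.10, 0.18 and 0.01, were called lower there, at -0.69, -0.84, -0.91 and -0.68 (camera adjusted p = 0.000293, 6.2e-06, 1.1e-05 and 0.0106). Smooth muscle, cholesterol synthesis and circadian lists were called lower too (medians -0.38, -0.27 and -0.43), and complement, immediate early and cardiac lists higher (1.01, 0.45 and 1.13). All of these 10 calls were lost when the correlation was estimated (adjusted p from 0.411 to 0.834 with an estimated correlation). The calls of club, goblet, neutrophil, erythroid, xenobiotic and NRF2 lists were lost there too (adjusted p from 0.0797 to 0.837). The interferon-stimulated list had a median of -1.71 without CuO replicate 1 (adjusted p = 5.4e-07, but adjusted p = 0.791 with an estimated correlation), and proliferation, glycolysis and mesothelium then had medians of 0.16, 0.23 and 0.40 in place of 0.44, 0.71 and 0.84. Neutrophil, xenobiotic, junction and NRF2 lists had medians of -1.05, -0.58, -0.31 and -0.20 without it, in place of -0.62, -0.11, -0.08 and -0.11. The erythroid call was lost there (adjusted p = 0.33), and oxidative phosphorylation was called higher (median 0.19, adjusted p = 0.00244, but adjusted p = 0.677 with an estimated correlation). As many as 18 lists were called in 53 of 100 simulated draws without any effect. Extracellular matrix genes were not called with all libraries (median 0.18, camera adjusted p = 0.357). Their median was -0.49 without CuO_TTM replicates 2 and 3, with 1 mouse left in that group. Without CuO replicate 1 it was -0.22, uncalled. Col1a1 differed by -0.11 with all libraries (95% interval -0.72 to 0.49).

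The 110 calls became 1 without CuO_TTM replicate 2 or without both replicates 2 and 3, 60 without CuO_TTM replicate 3 and 56 without CuO replicate 1. They became 69 without CuO replicate 3, 83 higher and 65 lower without CuO_TTM replicate 1, and 52, 52 and 54 without control replicate 1, 2 or 3, and no gene was called when the 6 libraries compared were fitted alone. No control library is part of this comparison, so leaving out a control changed the pooled spread and the libraries behind it, not the fold changes.

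**Figure D2:**
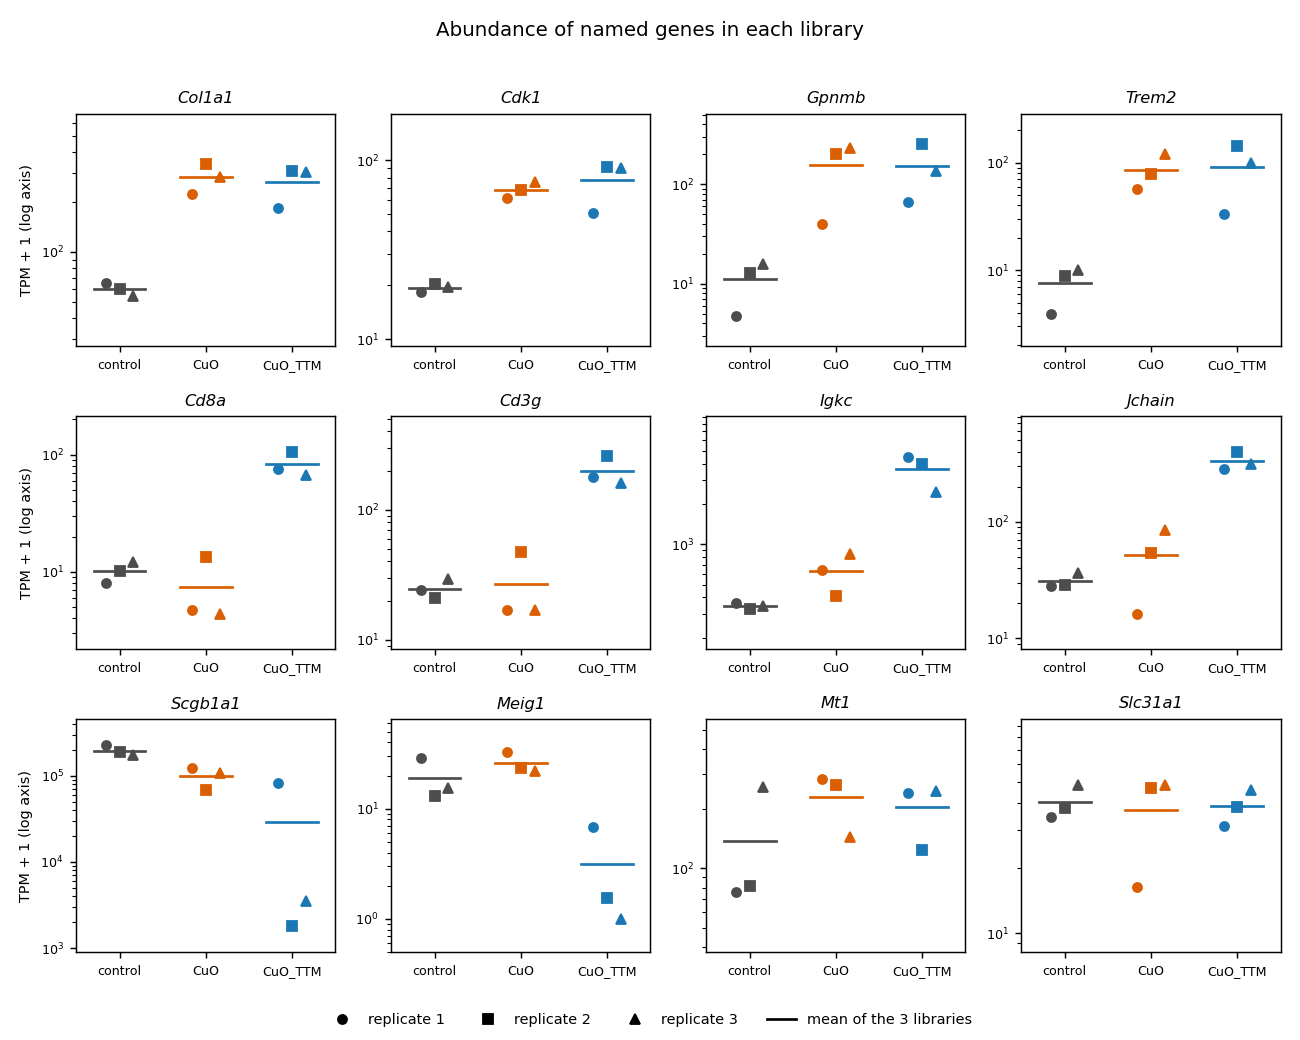
TPM + 1 of 12 named genes in each library on a log axis, with 1 point per library and a bar at the arithmetic mean of each group. Cd8a and Cd3g lay above all other libraries in the 3 CuO_TTM libraries, while Col1a1 and Cdk1 lay above the 3 control libraries in both CuO and CuO_TTM.

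The comparison of CuO_TTM with control shows how far lungs with both treatments were from those with neither. Some genes of the T cell, plasma cell, proliferation, matrix and lipid-laden macrophage lists passed the test over all genes and were higher in CuO_TTM. None of these 5 lists was called as a whole when the correlation was estimated (adjusted p from 0.256 to 0.464 with an estimated correlation). Gpnmb measured 152 ± 95.7 TPM against 10.1 ± 5.79 TPM in control (n = 3 each; log2 difference 3.75, limma adjusted p = 0.0441), and Trem2 and Ms4a7 were higher by 3.48 and 3.61. The matrix genes Tnc, which encodes tenascin C, and Col1a1 were higher by 3.06 and 2.11 (adjusted p = 0.0387 and 0.0182), and Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, by 1.63 (adjusted p = 0.0436). Cd8a, Cd3g, Cxcr6 and Pdcd1 were higher by 3.04, 2.99, 3.54 and 3.29, and Jchain, the joining chain of secreted antibodies, by 3.42. Among the named genes past the threshold, the largest falls were in Pon1 (-3.84), which encodes a serum esterase, Fabp1 (-3.18) and Meig1 (-3.04), followed by Npr3 (-2.18), Wdr66 (-2.02), Scgb1c1 (-2.02), Ccdc33 (-1.97), Ppbp (-1.80), Inmt (-1.74) and Gstm1 (-1.68), a glutathione transferase gene. Pon1, Meig1, Wdr66 and Ccdc33 were lower in both CuO_TTM replicates 2 and 3 than in replicate 1, like the airway lists. The other named genes that fell were not.

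limma called 277 genes higher and 17 lower, with 2795 at an unadjusted p under 0.05, and 68 of the 294 were antibody or T cell receptor segments. Of 100 draws simulated from the residuals without any effect, 3 gave at least 294 calls (median 0, largest 6340). In 36.8% of genes the 3 libraries of each group did not overlap, against 10% by chance. The median gene was 0.24 higher in CuO_TTM than in control (0.19 against CuO), and with quantile normalization, which moved that median to -0.03, the calls split into 227 higher and 64 lower. The proliferation list had a median of 1.66, with 29 of 30 genes higher over the list alone and 15 over all genes, among them Plk1 (1.85), Birc5 (1.96) and Cdk1 (1.94). T cell (median 2.31), plasma cell (2.36) and alternatively activated macrophage lists (1.57) had 13 of 14, 10 of 13 and 11 of 19 genes higher over the list alone and 9, 7 and 4 over all genes. These 4 lists and oxidative phosphorylation (median 0.48) were called by fry (adjusted p = 0.0078, 0.0195, 0.00707, 0.0456 and 0.00702), and they had adjusted p from 0.256 to 0.337 with an estimated correlation. The camera call of oxidative phosphorylation was lost with quantile normalization (adjusted p = 0.149). With median-ratio scaling its median was 0.23 and camera did not call it (adjusted p = 0.0641). fry was run with neither. Extracellular matrix genes had a median of 0.90, with 14 of 31 higher over the list alone and 5 over all genes (adjusted p = 0.464 with an estimated correlation), and neutrophil genes a median of -1.55, with 7 of 14 lower over the list alone and 0 over all genes (adjusted p = 0.256 with an estimated correlation). The neutrophil genes S100a8 and S100a9 differed by -2.36 and -2.30 and missed the threshold over all genes (adjusted p = 0.0728 and 0.0718), as did Scgb1a1 at -4.59 (adjusted p = 0.0808). Club and ciliated cell lists had medians of -2.58 and -1.85 (adjusted p = 0.256 each with an estimated correlation), and CuO_TTM replicates 2 and 3 again lay lowest. Camera called 30 lists, 13 higher and 17 lower, and 1 of 100 simulated draws without any effect gave as many. Monocyte, MHC class II, glycolysis, transitional epithelium, complement, matrix protease and lysosome lists were also called higher (adjusted p from 0.373 to 0.625 with an estimated correlation). Xenobiotic, capillary, endothelial, erythroid, platelet, goblet cell, heat shock, alveolar macrophage, immediate early, eosinophil and mast cell, cardiac, alveolar type 1 and fibroblast lists were also called lower (adjusted p from 0.256 to 0.633 with an estimated correlation). With quantile normalization, alveolar macrophage, eosinophil and mast cell, cardiac, fibroblast and interferon-stimulated lists were not called (adjusted p from 0.0875 to 0.403). The interferon-stimulated list was among those called lower although its median and mean were 0.01 (adjusted p = 0.832 with an estimated correlation). Camera compares a list with all other genes, and the median tested gene was 0.24 higher in CuO_TTM. B cell and natural killer cell lists were not called (medians 0.38 and -0.04, camera adjusted p = 0.811 and 0.336). Without CuO_TTM replicates 2 and 3, B cell, natural killer cell and interferon-stimulated lists had medians of 1.48, 0.95 and 1.77. That fit leaves 1 mouse in the CuO_TTM group, so only its medians are given, and they describe that mouse. Inflammasome, cytokine and dendritic cell lists stood at 0.89, 1.23 and 1.13 there. Cholesterol synthesis, surfactant, junction, circadian, alveolar type 2 and smooth muscle lists stood at -0.24, -0.68, -0.51, -0.61, -0.80 and -0.34. Medians of lysosome, immediate early, goblet cell, eosinophil and mast cell, platelet and cardiac lists were 0.52, -0.05, -0.36, -0.75, -0.39 and 0.44. Those of proliferation, matrix, neutrophil, club and ciliated cell lists were 1.36, 0.45, -1.51, -1.31 and -0.61. Without CuO replicate 1, 29 proliferation, 11 matrix and 8 alternatively activated macrophage genes were called over all genes, 20 of 24 oxidative phosphorylation genes passed over the list alone, and no erythroid gene did, in place of 6. In that fit 6 neutrophil, 9 xenobiotic, 4 club and 3 ciliated cell genes were called lower over all genes, in place of 0 in each list. The TCA cycle list, uncalled with all libraries, was called higher in it (camera adjusted p = 0.0181, but adjusted p = 0.504 with an estimated correlation).

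The 294 calls became 1 without both CuO_TTM replicates 2 and 3, 1660 without CuO replicate 1, 215 higher and 106 lower without CuO_TTM replicate 1, 8 and 12 without CuO_TTM replicate 2 or 3, and 8, 3 and 29 without control replicate 1, 2 or 3. When the 6 libraries compared were fitted alone, 1378 genes were called. No CuO library is part of this comparison, so leaving out CuO replicate 1 changed the pooled spread and the libraries behind it, not the fold changes.

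Across the 3 groups together, limma's F test called 186 of 15487 genes, with 2142 at an unadjusted p under 0.05. Without CuO replicate 1 the count was 823 and without CuO replicate 3 it was 94. It was 4 without CuO_TTM replicate 2 or 3, and 24, 0 and 55 without control replicate 1, 2 or 3. Of the genes called higher in CuO_TTM against CuO, 88 were also called higher against control, where independent lists would share 1.91, and 1 of the 3 lower genes was also lower. Both comparisons contain the CuO_TTM libraries, so part of this overlap may come from the shared libraries.

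The last comparison asked whether CuO_TTM against CuO ran opposite to CuO against control. Across 15487 genes the fold changes correlated at -0.19 (Pearson) and -0.22 (Spearman). Both comparisons contain the CuO libraries, and libraries simulated without any effect gave a median correlation of -0.47 (95% of 100 draws from -0.95 to 0.66). The covariance was -0.0538, against a simulated median of -0.0503 (95% of draws from -0.321 to 0.0652), a difference of -0.00349. No gene was called in both comparisons with opposite signs, because none was called in CuO against control. CuO against control and CuO_TTM against control, which share the control libraries, correlated at 0.56 (Pearson) and 0.61 (Spearman) across genes, against a simulated median of 0.60 (95% of draws from -0.49 to 0.96). Their covariance was 0.185, within the range of simulated values (median 0.0699, 95% of draws from -0.0402 to 0.383).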

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

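The alternatives of median-ratio scaling, Scgb1a1 left out, trend removal, library weights, 2 libraries left out together and an estimated correlation with libraries left out were chosen after seeing the data, and the other alternatives before. In CuO against control, 0 genes became 3 with no filter, 3 with the replicate block, 7 with median-ratio scaling, 29 with the length and GC trend removed and 412 with library weights. In CuO_TTM against CuO, 110 became 30 with no filter, 67 with a mean of at least 5 TPM, 41 with a pseudocount of 0.1, 0 with only the 2 groups compared, 66 with the trend removed, 1192 with weights and 1 without CuO_TTM replicates 2 and 3. In CuO_TTM against control, 294 became 56 with no filter, 183 with the pseudocount, 113 with the block, 1378 with only the 2 groups, 121 without Scgb1a1, 7670 with weights and 1 without CuO_TTM replicates 2 and 3. For any group, 186 became 24 with no filter, 96 with the pseudocount, 73 with the block, 88 without Scgb1a1, 6681 with weights and 0 without CuO_TTM replicates 2 and 3. CuO replicate 1 had the lowest library weight, 0.0798, and CuO_TTM replicate 2 the highest, 17.04. CuO_TTM replicates 1 and 3 had weights of 0.34 and 0.995, so with weights the CuO_TTM mean rested mostly on replicate 2. Without CuO_TTM replicates 2 and 3, the lone CuO_TTM library was assumed to vary like the other groups. Leaving out 1 library gave 0 to 35 genes in CuO against control (35 without CuO replicate 1), 1 to 148 in CuO_TTM against CuO (1 without CuO_TTM replicate 2), 3 to 1660 in CuO_TTM against control (1660 without CuO replicate 1, 3 without control replicate 2) and 0 to 823 for any group. CuO_TTM against control contains no CuO library, and CuO_TTM against CuO no control library. Where such a library was left out, the fold changes stayed the same, and only the pooled spread and the libraries behind it changed. Beyond this, no cause of these counts was tested. The count of opposite calls, 0, became 1 with no filter and 1 with the trend removed. Of the 110 genes of CuO_TTM against CuO, 88 were also called with quantile normalization and 84 with median-ratio scaling. In CuO_TTM against control, median-ratio scaling split the calls into 215 higher and 49 lower, and trend removal into 229 and 101. Trend removal split the lists of CuO_TTM against CuO into 9 higher and 5 lower. Count models and their normalizations, foreseen for a table of counts, were not run, because the table holds TPM.

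The 26, 18 and 30 lists called by camera became 0, 0 and 0 with an estimated correlation, also with CuO replicate 1 or CuO_TTM replicates 2 and 3 left out, and 0, 2 and 5 with fry. Same-numbered libraries of different groups had deviation correlations from -0.37 to 0.29. These gave no sign that the numbers pair the mice, but so few libraries cannot exclude it. The replicate block gave 81 genes in CuO_TTM against CuO. Among named genes, 0 called results reversed. Over the settings other than leaving out a single library, called results were kept 544 times and lost 182 times. Uncalled results gained a call 323 times. These settings include the fit without both CuO_TTM replicates 2 and 3. Over the single libraries left out, the numbers were 261, 243 and 104. Uncalled genes changed sign and stayed uncalled 153 times. The correlation of opposite changes was -0.40 to -0.14 over the settings run. TPM keep no depth, so what depth limits is unknown.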

Other observations

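Of the tests below, those of length and GC trend and of the most abundant genes in CuO replicate 1, and the counts of other splits, were written before their results were seen. All other tests in this part were chosen after the values were seen.

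Interferon-stimulated genes and inflammatory chemokines differed between mice within groups. The interferon-stimulated list stood at 1.31 in control replicate 3, 2.20 and 0.92 in CuO replicates 2 and 3 and 1.82 in CuO_TTM replicate 1, and at -0.59 to -1.85 in the other 5 libraries, relative to the control mean on the log2 scale. The list of inflammatory cytokines and chemokines stood at 2.26 in CuO replicate 2 and at 0.99 in control replicate 3, with CuO_TTM replicate 1 between them, and at -0.63 to 0.77 in the other 6 libraries. Cardiac muscle genes stood at 1.76 in control replicate 1 and 0.58 in CuO_TTM replicate 1, and at -1.54 to -0.03 in the other 7 libraries.

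CuO replicate 1 stood apart from the other CuO libraries, with a mean correlation of 0.875 to them. After each library's trend with transcript length and GC content was removed, that mean was 0.887, still under 0.923, the lowest other pair within a group, which argues against the trend as the whole cause. With the 20 most abundant genes left out, its median gene lay at -0.41, against -0.14 to 0.17 in the other libraries, which argues against a few genes taking most of the TPM. It lay above all 3 controls in 29 of the 35 genes called without it, which argues against a control library labelled CuO. RNA quality and depth stay open, because the table holds neither, and no biological explanation was tested.

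T cell and plasma cell genes were higher in CuO_TTM than in CuO, with a median of 2.55 over 27 genes, and 2.77 with CuO_TTM replicate 1 as the only library of its group. Airway-poor tissue in replicates 2 and 3 would raise all other cell types alike, but the highest of 6 lists of alveolar, vascular and stromal cells stood at 0.64 above CuO, against 2.30 for T cells, and with median-ratio scaling 83 of the 107 higher genes stayed called, which argues against scaling. Lymph node tissue would bring B cell genes, whose list reached at most 0.049 in replicates 2 and 3, within the control range of -0.77 to 0.58 but above all 3 CuO libraries (-0.91 to -0.50), so it stays open there. In replicate 1 the B cell list stood at 1.65, above all controls, and alveolar type 1 and type 2 lists at -0.95 and -0.86, the lowest of the 9 libraries, so lymphoid tissue in that piece may contribute and stays open too. An effect of TTM on lymphocytes in the lung stays a hypothesis, untested beyond these 3 mice.

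Airway genes were low in CuO_TTM replicates 2 and 3. Medians of the abundant club and ciliated cell genes lay at -3.38 and -3.13 relative to the controls. Less airway tissue in these 2 pieces and a loss of airway cells with TTM both predict this, so these medians support neither, and the explanations cannot be told apart. CuO_TTM replicate 1 stood at -0.54 for ciliated cells, within the range of the CuO libraries (-0.82 to 0.29) only through CuO replicate 1. This value lay below CuO replicates 2 and 3 (0.14 and 0.29) and below the lowest control (-0.36), but 1 library decides nothing.

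Each comparison of 3 with 3 libraries has only 10 splits, too few for a share under 0.05. In CuO_TTM against CuO the real split gave 110 genes and the highest other 12 (1 of 10 splits as large). In CuO_TTM against control it gave 294 and the highest other 2 (1 of 10), and in CuO against control 0 and 1 (10 of 10). For lists the real splits gave 26, 18 and 30 calls and the highest others 25, 28 and 27 in CuO against control, CuO_TTM against CuO and CuO_TTM against control (1, 6 and 1 of 10 splits as large). For any group, only 1 of 100 splits of the 9 libraries gave as many as 186 genes, and that was the real split itself. The test could give no smaller share, so a count as large was rare among these splits but chance is not excluded. The highest other split gave 162, and it kept the CuO_TTM libraries together while mixing control and CuO.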
